A study of Mus musculus with 2 samples.

How the data were processed

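H3K4me2 ChIP-seq was carried out on the stomach of mouse embryos at embryonic day 15.5 in 2 biological replicates of 1 group, taken as such from the labels, which give a pool of 78 embryos for the first and 62 for the second. The authors aligned the reads to mm10, filtered the alignments and called peaks against 2 control alignments, per the readme texts deposited with the libraries; the aligner and the peak caller are not given in the sources used here. The control alignments and the read alignments themselves were not used here. Peaks were called on each replicate alone and on both replicates pooled, and a replicated list was derived from these, by a rule not given in the sources used here. Each peak carried a signal value, deposited by the authors for the peak against control, and −log10 p and −log10 q values, likewise as deposited by the authors. The lowest −log10 p of the 4 lists, per the authors' deposited tables, lay between 2.01 and 2.17. Signal was used only to rank and describe peaks within a list. No source used here puts the signal of different lists on 1 scale, so a peak's signal was never compared between replicates.

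The lists give neither read counts nor library sizes. The depth is therefore unknown, and with it the reason why the lists differ in length and width; a deeper library can give more and wider peaks. Peaks on chromosomes 1 to 19, X and Y were analysed, 39025 of the replicated list. Coordinates were written 1-based. Genes, starts and exons came from the mm10 gene annotation supplied with the reference genome: 21911 protein-coding genes, after keeping the first gene identifier of 27 symbols held by more than 1 gene. Of 385 list members written in 20 gene lists before the data were examined, 384 were found, 1 of them through an older symbol.

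A promoter peak was a peak within 1 kb of any annotated start of a protein-coding gene. Covered length was the number of bases under peaks within 10 kb either side of the gene's 5' end, which can include peaks of neighbouring genes. A gene marked only at an alternative start far from its 5' end has a promoter peak and a covered length of 0. Distal peaks lay more than 2.5 kb from any annotated start and were counted within 50 kb of the 5' end. The ratio of observed to expected CpG was computed in 1 kb around the 5' end. Domains joined replicated peaks no more than 1 kb apart. For each gene value the mean and SD over 2 replicates came from the replicates' own lists, while tests used the replicated list.

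Overlap between replicates required at least 50% of the peak's length. It was compared with 1000 random rotations of those peaks along each chromosome, with the other list kept in place (permutation test, one-sided). Promoter shares were compared with 1000 rotations of the peaks in the same way. Lists were tested by promoter peak with Fisher's exact test, and by covered length and number of distal peaks with permutation tests against 100000 random gene sets of the same size, all two-sided and with Benjamini-Hochberg adjustment over the 20 lists at a threshold of 0.05. Differences between classes of lists used 100000 permutations of the class labels. Motifs were 18 consensus words, searched on both strands, and compared between distal peaks and windows 5 kb to either side that held no peak, in a logistic model with GC and CpG content as covariates and the same adjustment; 353 words with shuffled letters, up to 20 per motif, were run in the same model. Genes stand in these tests as units that describe these libraries, and neighbouring genes are not independent. Intervals of shares are Wilson or exact binomial 95% intervals, cover counting error only and take peaks or genes as independent.

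Genes named in the text followed a rule fixed before the data were examined: in each list the 3 members with the largest mean covered length and up to 3 members, first in alphabetical order, with no replicated promoter peak; the 20 protein-coding genes with the largest covered length; all Hox genes; genes in the 10 widest domains; and the nearest genes of the 5 strongest peaks more than 10 kb from any start. Other genes are said to have been named after their values were seen. Not every gene under the rule is printed.

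Alternatives planned before the data were examined were, for the whole lists, an overlap of 1 bp and of 50% of both peaks, equal numbers of peaks per list, the stronger 50% of peaks, the pooled list, each replicate's own list, promoter distances of 500 bp and 2.5 kb, starts limited to the 5' end, windows of 5 kb and 100 kb, domain width in place of covered length, genes matched on 10 classes of promoter CpG content, motif control windows at 10 kb, and other gaps for domains. Added after seeing the data were an overlap of 1 bp in classes of peak strength, the replicated peaks that met the overlap rule with both replicates, the width of the peak as a further motif covariate, shuffled words, the X chromosome by CpG class, the pooled list and each replicate's own list for CpG classes and domains, each replicate's own list for Hox clusters, and the stomach class without its mesenchymal and epithelial lists. The pooled list for Hox clusters was planned.

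The tests were first tested on simulated data. Among 1000 random lists of 20 of the 21911 genes, at a p of 0.05 without adjustment, 5.8% were called with no change, 49.3% with 1000 bp of cover added to every member and 99.1% with 2000 bp added. The reported lists hold 11 to 30 genes and were called after adjustment, so their rates of detection were not measured. The test between classes called 6% of 200 unchanged draws and 100% with 1500 bp added. The motif model called 5% of 200 unchanged draws and 100% with a log odds of 0.4, which it estimated at 0.406. The simulated words followed GC content just as the model assumes, in equal numbers of peaks and windows. Rates of false calls for the real words were therefore not measured. Covered length and peak counts were checked against bedtools on 500 simulated intervals and were equal in all of them. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9, beside samtools 1.23.1 and bedtools 2.31.1. Peaks on unplaced or unlocalized scaffolds were left out, because genes and starts were taken from the chromosomes alone.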

Results

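Chromatin from the stomach of B6NCrl mouse embryos at embryonic day 15.5 was immunoprecipitated for histone H3 dimethylated at lysine 4 (H3K4me2), a mark found at promoters and at distal regulatory elements, and the recovered DNA was sequenced. There was 1 group of 2 biological replicates, a pool of 78 embryos for replicate 1 and a pool of 62 embryos for replicate 2, both of mixed sex. At this stage the stomach consists of a simple endodermal epithelium, a forestomach lining, a thick mesenchyme in which smooth muscle forms, and enteric neural crest cells. Peaks were given on genome build mm10 for each replicate, for both replicates pooled, and as a replicated list. Replicate 1 had 54401 peaks that covered 51.8 Mb, with a median width of 551 bp, and replicate 2 had 55494 peaks that covered 46.9 Mb, with a median width of 456 bp. The replicated list held 39039 peaks that covered 51.7 Mb, 1.90% of the chromosomes, with a median width of 964 bp. The files hold peaks and no read counts, so the depth of each library is unknown. With a single group the design holds no contrast between conditions, so the replicates were compared with each other and genes were compared with other genes within these libraries.

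The strongest sites of the mark were shared by both pools, and weak ones less often. Of the peaks of replicate 1 on the chromosomes, 35048 of 54386 (64.4%, Wilson 95% interval 64.0 to 64.8) were covered over at least 50% of their length by peaks of replicate 2, and of those of replicate 2, 40032 of 55477 (72.2%, 71.8 to 72.5) were covered by replicate 1. The peaks of both replicates shared 41.1 Mb of a union of 57.6 Mb, which was 79.3% of the length covered in replicate 1 and 87.6% of that in replicate 2. Random rotation of the replicate's own peaks along each chromosome, with the other list kept in place, gave mean shares of 1.79% and 2.02% (one-sided permutation test, p = 0.001 for each replicate, the smallest that 1000 rotations can give). Ranked within its own list by the authors' signal value, the stronger 50% of replicate 1 was covered at 96.5% and that of replicate 2 at 98.7%, while the weaker 50% was covered at 32.4% and 45.7%. The strongest 10% of each list was covered at 100%, and 89.9% of its peaks lay within 1 kb of the start of a protein-coding gene in each replicate. In the weakest 10%, 18.0% of replicate 1 peaks and 27.2% of replicate 2 peaks were covered, and 13.2% and 14.1% lay at such starts. These intervals cover counting error only.

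**Figure D1:**
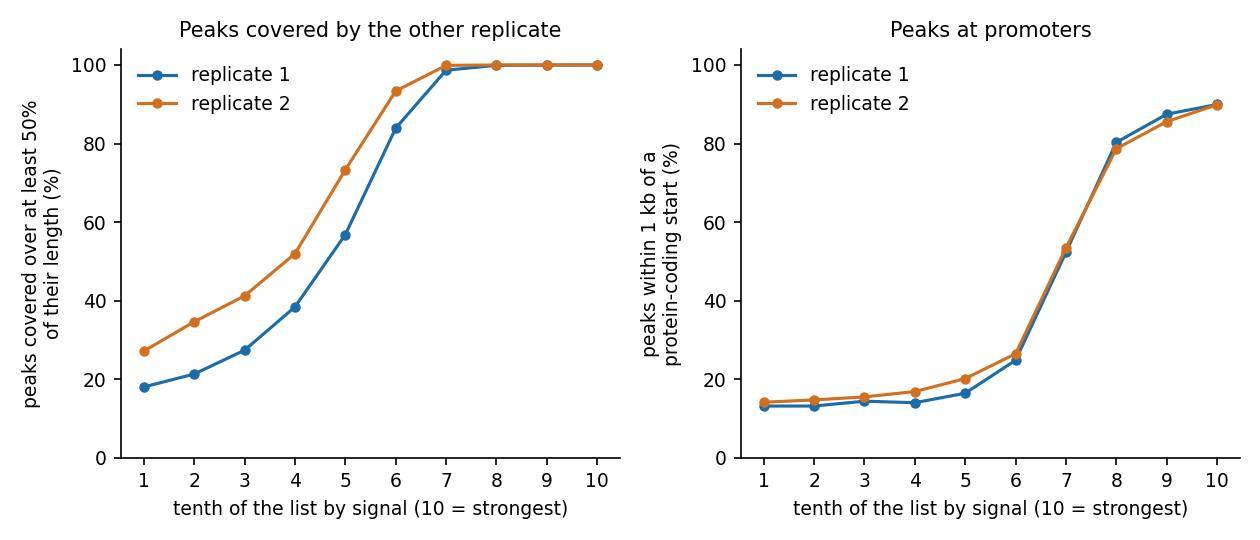
Left, share of each replicate's peaks covered over at least 50% of their length by peaks of the other replicate (%), in 10 equal classes of the list ranked on signal; right, share of the same peaks within 1 kb of a protein-coding start (%). Lines join the classes of replicate 1 (blue) and replicate 2 (orange); coverage ran from 18.0% and 27.2% in the weakest class to 100% in the strongest.

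The replicated list was contained in the pooled list, of which it made up 70.7%. Overlap over at least 50% of either peak with peaks of both replicates gave 35951 pooled peaks, all of them in the replicated list, which held a further 3088. On the chromosomes, 2319 of these further peaks met that rule with replicate 1 alone, 728 with replicate 2 alone and 40 with neither. The peaks that did not meet the rule were weak and narrow, with a median signal of 3.20 and a median width of 376 bp against 10.6 and 1066 bp for those that met it, and they made up 2.47% of the covered length. The 16142 pooled peaks outside the replicated list had a median width of 247 bp.

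Most protein-coding genes carried H3K4me2 at a start in the embryonic stomach. A replicated peak lay within 1 kb of an annotated start in 15094 of 21911 protein-coding genes (68.9%), and the replicates' own lists marked 15250.5 ± 9.19 genes (SD, n = 2), of which 15054 were marked in both, 190 in replicate 1 alone and 203 in replicate 2 alone. Promoters took 19269 of 39025 replicated peaks (49.4%, exact 95% interval 48.9 to 49.9), and 41.1% ± 0.663 (n = 2) of the peaks of each replicate. The peaks at promoters were broad, with a median width of 1732 bp against 601 bp elsewhere. Rotated peaks met a promoter in 6.06% of cases, an 8.15-fold difference (one-sided permutation test, p = 0.001, the smallest that 1000 rotations can give). By its summit, 46.2% of replicated peaks lay within 1 kb of a start, 26.7% between genes, 23.1% in introns, 2.74% in exons other than untranslated regions and 1.38% in untranslated regions, against 58.7% between genes and 34.5% in introns after rotation. More than 2.5 kb from any start lay 14513 peaks (37.2%).

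Almost all genes with a 5' end rich in CpG had a promoter peak. Where the observed to expected CpG ratio in 1 kb around the 5' end was over 0.6, 9913 of 10061 genes had a replicated promoter peak (98.5%, exact 95% interval 98.3 to 98.8). Between 0.4 and 0.6 the share was 2701 of 3078 (87.8%, 86.5 to 88.9), and under 0.4 it was 2480 of 8772 (28.3%, 27.3 to 29.2). The mean length covered within 10 kb either side of the 5' end followed the same order, at 3.38, 2.66 and 0.871 kb. At CpG-rich promoters the mark reached further into the gene than away from it: cover was highest at 95.9%, 450 bp downstream of the 5' end, and stood at 30.5% in the bin 2 kb downstream and at 7.84% in the bin 2 kb upstream. No test was made of these shares. A promoter peak could lie at any annotated start of the gene, so the marked start need not be the one classed by CpG. Under a ratio of 0.4, mean cover of 100 bp bins around the 5' end was at most 14.9%.

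**Figure D2:**
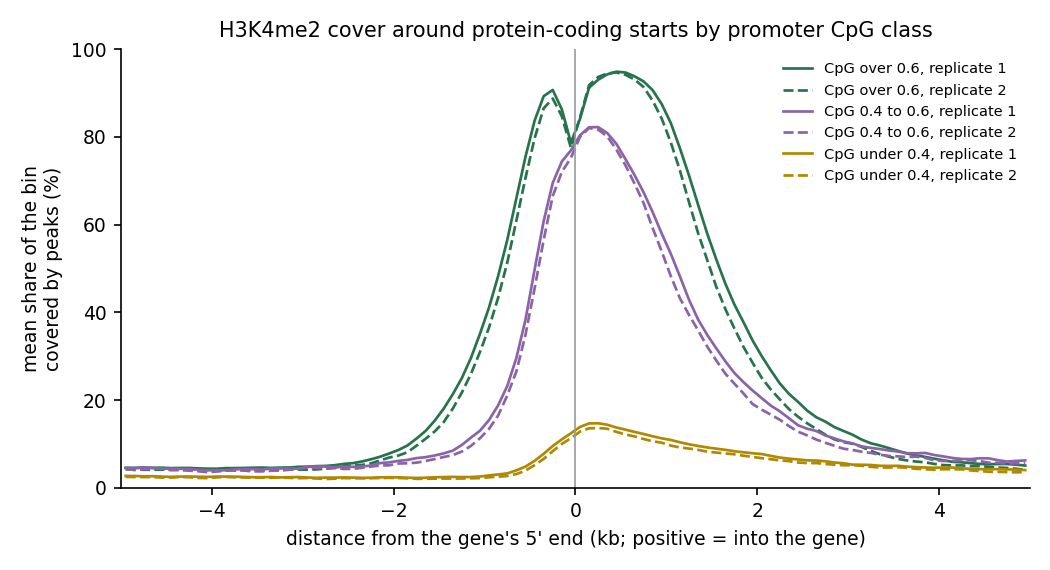
Mean share of 100 bp bins covered by peaks (%) against the distance from the gene's 5' end (kb, positive into the gene), for promoters with a CpG ratio over 0.6 (green), from 0.4 to 0.6 (purple) and under 0.4 (yellow), in replicate 1 (solid) and replicate 2 (dashed). Cover of CpG-rich promoters dipped at the 5' end itself and extended further into the gene than upstream of it; in the replicated list it was 30.5% in the bin 2 kb downstream and 7.84% in the bin 2 kb upstream.

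Regulators of the stomach epithelium and of the gastric mesenchyme were marked at every promoter examined, while the genes that mature gastric glands use to make mucus, acid and pepsinogen were mostly bare. The lists of genes were fixed before the data were examined, and each test treats genes as units within these libraries; genes are not replicates of the tissue. All 26 epithelial regulators and junction genes, among them the endodermal transcription factors Gata6, Foxa1 and Foxa2, had a replicated promoter peak, as did all 30 mesenchymal genes, among them the homeobox genes Meis1 and Meis2 and the forkhead gene Foxf1. So did 22 of 23 genes of smooth muscle and interstitial cells of Cajal, the pacemaker cells of the gut; the exception was Casq2, a calcium store protein of muscle. Of 20 secretory and acid genes 4 were marked: the membrane mucin Muc1, the goblet and mucous cell factor Spdef, the proton pump subunit Atp4a, and the protease Ctse, of which the last was named after its value was seen. No replicated peak covered the 5' end of Atp4a itself. The second proton pump subunit Atp4b, the chitinase Chia1 and the hormone gene Gast had no promoter peak. By Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 lists, the shares were above those of other genes for the epithelial regulators (adjusted p = 0.000533), the mesenchyme (0.000273) and smooth muscle (0.00732), and below for the secretory and acid genes (0.000186). The last call ended against genes of the same promoter CpG content, where the difference was -13.8 percentage points (adjusted permutation p = 0.554) in place of -48.9. The calls of mesenchyme and smooth muscle ended with the stronger 50% of peaks.

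The signalling and housekeeping lists were marked throughout. All 28 genes of Hedgehog, BMP, FGF, Notch and retinoic acid signalling, all 21 genes of Wnt signalling and all 20 housekeeping genes had a replicated promoter peak (Fisher's exact test, adjusted p = 0.000284, 0.00189 and 0.00278). Below other genes stood the germ cell list with 2 of 13 (adjusted p = 0.000525, exact test), leukocytes with 5 of 15 (0.0192), and intestinal epithelium and hepatocytes with 6 of 16 each (0.0218). Among the unmarked genes were the germ line helicase Ddx4, the macrophage receptors Adgre1 and Csf1r, the intestinal alkaline phosphatase Alpi and serum albumin, Alb. The other lists did not pass the exact test: forestomach squamous epithelium had 10 of 20 (adjusted p = 0.126), enteric neurons and glia 19 of 23 (0.223), endothelium 13 of 20 (0.852), erythroid cells 4 of 11 (0.0662), mesothelium 11 of 12 (0.160), pancreas 9 of 16 (0.318), cardiac muscle 11 of 16 (1), skeletal muscle 9 of 17 (0.223) and the central nervous system 19 of 21 (0.0552). From the list of replicate 1 alone, without replicate 2, 3 lists stood below in place of 5, leukocytes and hepatocytes being lost. With the pooled list 4 stood below, since the same lists were lost and erythroid cells came to pass. With the stronger 50% of peaks 8 lists stood below, with forestomach, erythroid cells and skeletal muscle gained. Against genes of the same promoter CpG content, 4 lists stood above (epithelium, mesenchyme, smooth muscle and the Hedgehog, BMP, FGF, Notch and retinoic acid list) and 1 below (germ cells). The calls of leukocytes, hepatocytes, intestinal epithelium, housekeeping genes and Wnt genes ended there, and intestinal epithelium changed sign, to 5.31 percentage points above its matched genes.

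Among the 20 lists, cover was widest around the genes of the gastric mesenchyme. Within 10 kb either side of the 5' end, replicated peaks covered a mean of 8.91 kb around the mesenchymal genes, against 2.28 kb for all protein-coding genes, and the replicates' own lists gave 8.45 ± 0.579 kb (SD, n = 2). Meis2 (chromosome 2, 115863064 to 116065839), a homeobox partner of Hox proteins, was covered over 18.9 ± 1.01 kb, Foxf1 (chromosome 8, 121084386 to 121088144), a Hedgehog target of visceral mesoderm, over 16.6 ± 0.746 kb, and Meis1 (chromosome 11, 18879817 to 19018985) over 15.1 ± 0.40 kb (n = 2 each). Behind Meis1 came the nuclear receptor gene Nr2f2, at 13.4 ± 0.267 kb. Barx1 (13.0 ± 0.345 kb), a homeobox gene of the stomach mesenchyme that was named after its value was seen, stood below Nr2f2. Around the epithelial regulators the mean was 5.70 kb (replicates 5.30 ± 0.627), with Gata6 (chromosome 18, 11052064 to 11085635) at 10.8 ± 0.931 kb, Foxa1 (chromosome 12, 57540628 to 57546916) at 10.5 ± 1.35 kb and Foxa2 (chromosome 2, 148042877 to 148046969) at 10.1 ± 0.816 kb. Sox2, a foregut factor and likewise named after its value was seen, was covered over 7.09 ± 1.67 kb. Permutation tests against 100000 random gene sets of the same size, two-sided and adjusted over the 20 lists, gave an adjusted p = 1e-04 for both lists, from the smallest p that these permutations can give.

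Genes of Hedgehog, BMP, FGF, Notch and retinoic acid signalling had a mean cover of 5.70 kb (replicates 5.44 ± 0.392), led by the BMP target Id3 at 10.01 ± 0.604 kb, the retinoic acid receptor Rara at 9.35 ± 0.307 kb and the Notch target Hes1 at 9.27 ± 0.513 kb. Housekeeping genes had 5.20 kb (4.83 ± 0.337), led by the elongation factor Eef2 at 9.20 ± 1.12 kb, and genes of Wnt signalling 4.80 kb (4.62 ± 0.357), led by the receptor Fzd2 at 7.76 ± 0.791 kb. Smooth muscle genes had 3.67 kb (3.35 ± 0.479), with the tropomyosins Tpm1 at 9.64 ± 0.696 kb and Tpm2 at 6.13 ± 0.110 kb and the muscle regulator Srf at 5.62 ± 0.0919 kb. All 4 lists stood above random sets (adjusted permutation p = 1e-04, 1e-04, 0.00016 and 0.0149), but the smooth muscle call was lost with the list of replicate 2 alone, without replicate 1, and with the stronger 50% of peaks. Below random sets stood the secretory and acid genes at 0.839 kb (adjusted permutation p = 0.0024), intestinal epithelium at 1.03 kb and hepatocytes at 1.04 kb (0.0221 each) and germ cells at 0.952 kb (0.0248). Of these, germ cells alone stayed below genes of the same promoter CpG content, but were lost with the stronger 50% of peaks; all 6 lists above stayed above CpG-matched genes.

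The remaining 10 lists did not pass the covered-length test, and some of them held single genes with wide cover. Among enteric neural crest genes, with a mean of 2.97 kb (adjusted permutation p = 0.222), Hand2, which acts in neural crest and in mesoderm, was covered over 12.05 ± 2.22 kb and the neuregulin receptor Erbb3 over 6.05 ± 0.151 kb, while the glial gene Plp1 had none. Among endothelial genes, with 2.83 kb (0.306), the lymphatic factor Prox1 had 6.84 ± 0.0990 kb and Fli1 6.49 ± 0.684 kb, and the sialomucin Emcn had none. Pancreas genes averaged 2.40 kb (0.817), with the transcription factors Mnx1 at 7.79 ± 1.37 kb, Nkx6-1 at 6.08 ± 0.822 kb and Pdx1, which also acts in the antrum and duodenum, at 5.22 ± 1.12 kb. The digestive enzyme genes Cela2a, Cpa1 and Ctrb1 had no promoter peak, but Cpa2, named after its value was seen, had one. Mesothelial genes averaged 2.24 kb (0.991), with Wt1 at 5.22 ± 0.880 kb. Forestomach genes averaged 1.68 kb (0.269), with the keratin Krt15 at 5.78 ± 1.21 kb and Pax9 at 4.71 ± 0.459 kb. No replicated peak covered the 5' end of Krt15 itself. The central nervous system list averaged 2.87 kb (0.270), cardiac muscle 1.70 kb (0.311), skeletal muscle 1.60 kb (0.258), leukocytes 1.45 kb (0.213) and erythroid cells 1.39 kb (0.232).

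**Figure D3:**
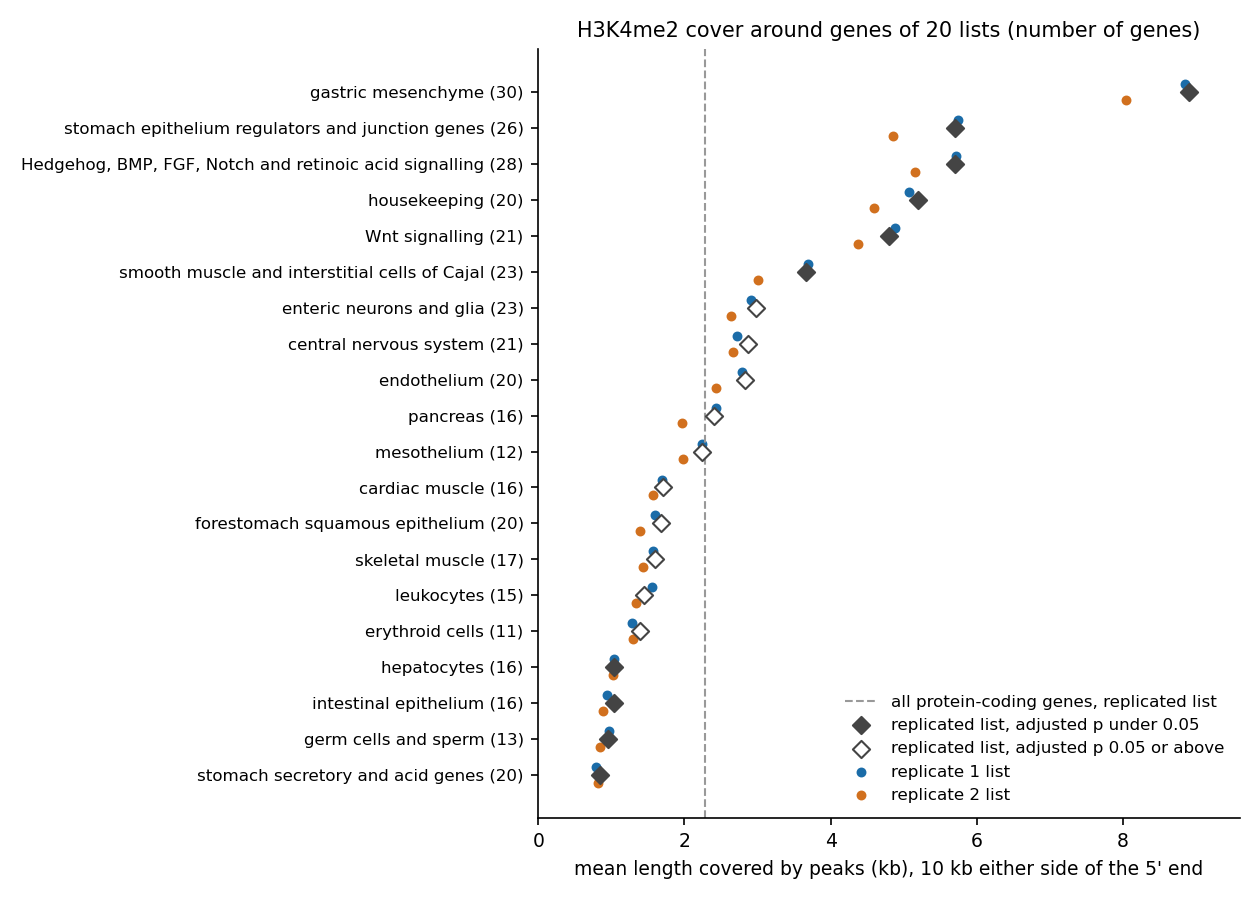
Mean length covered by peaks within 10 kb either side of the 5' end (kb) for each of 20 gene lists, with the number of genes in parentheses; diamonds give the replicated list (filled, adjusted p under 0.05) and points the lists of replicate 1 (blue) and replicate 2 (orange), beside all protein-coding genes (dashed line, 2.28 kb). The gastric mesenchyme lay highest, at 8.91 kb, and the secretory and acid genes lowest, at 0.839 kb.

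Taken as classes, genes of the stomach's own tissues had wider cover than genes of other organs, a difference carried mostly by the mesenchymal and epithelial lists. The 174 genes of the lists for stomach epithelium, mesenchyme, muscle, nerve, vessel and mesothelium averaged 4.04 kb, the 67 genes of heart, skeletal muscle, brain and germ cells 1.90 kb, and the 48 genes of intestine, pancreas and liver 1.49 kb. The difference was 2.14 kb (SE 0.356, permutation of class labels, two-sided, p = 3e-05) from the other tissues and 2.55 kb (SE 0.408, permutation p = 5e-05) from the neighbouring organs. In replicate 1 the differences were 2.16 and 2.54 kb and in replicate 2 they were 1.79 and 2.24 kb. Without the mesenchymal and epithelial lists, an alternative chosen after seeing the data, the remaining 118 stomach genes averaged 2.43 kb. The difference was then 0.534 kb (SE 0.304, permutation p = 0.114) from the other tissues, which did not pass the test. It was 0.940 kb (SE 0.365, permutation p = 0.0185) from the neighbouring organs. The number of distal peaks did not differ detectably between the classes, at a mean of 1.65 per stomach gene against 1.37 in the other tissues (permutation p = 0.319) and 1.5 in the neighbouring organs (permutation p = 0.649). The secretory and forestomach lists counted in the stomach class, although they lay below the mean of all genes.

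Distal peaks were more frequent near the genes of 8 lists, pancreas and housekeeping genes included, than near random genes. Counting replicated peaks more than 2.5 kb from any start and within 50 kb of the 5' end, all protein-coding genes had a mean of 0.840. The Hedgehog, BMP, FGF, Notch and retinoic acid list had 3.18, epithelial regulators 2.85, pancreas genes 2.63, mesenchymal genes 2.60, Wnt genes 2.52, housekeeping genes 2.25, endothelial genes 1.90 and genes of the central nervous system 1.86. The homeobox genes Nkx6-1 and Pdx1 had 9 and 7 such peaks, Rara and Hes1 had 7 each, and Cdx2, the intestinal regulator, had 6. The 5' ends of Pdx1 and Cdx2 lie at 147269959 and 147307270 of chromosome 5, so their windows overlap and can count the same peaks. These 8 lists stood above random sets (adjusted permutation p = 0.000133, 0.000133, 0.00096, 0.000133, 0.0005, 0.0018, 0.0165 and 0.0165, in that order), and the other 12 did not pass the test. Among the 12 were smooth muscle with 1.09, enteric neurons and glia with 0.957 and mesothelium with 0.750. Endothelium and the central nervous system were lost with the list of either replicate alone and with the pooled list, and the central nervous system also within 100 kb. With only the stronger 50% of replicated peaks, 2 lists stood above: mesenchyme and the Hedgehog, BMP, FGF, Notch and retinoic acid list.

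Along the Hox clusters, which pattern the body axis, the mark lay over most anterior and central genes of Hoxa and Hoxb and was sparser over their posterior genes. By the share of annotated spans, Hoxd did not follow this order throughout. Peaks covered 53.8% ± 3.47 (SD, n = 2) of the Hoxa cluster (chromosome 6, 52155590 to 52260880), 38.6% ± 2.52 of Hoxb (chromosome 11, 96194316 to 96368256), 18.3% ± 1.44 of Hoxc (chromosome 15, 102921103 to 103036852) and 17.1% ± 0.410 of Hoxd (chromosome 2, 74668310 to 74765142). The Hoxb span is the longest and includes a stretch without Hox genes, from 96197447 to 96271457. By length, replicated peaks covered more of Hoxb, 71.0 kb, than of Hoxa, 59.7 kb. Within Hoxa the spans of Hoxa2, Hoxa4 and Hoxa5 were covered at 93.7% ± 0.878, 98.2% ± 2.55 and 94.4% ± 2.62, Hoxa7 at 54.7% ± 8.84, and Hoxa9, Hoxa10 and Hoxa11 at 19.4% ± 8.23, 6.20% ± 2.14 and 10.4% ± 6.68. Hoxa13, at the end of the cluster, had 31.2% ± 1.02. Within Hoxb, Hoxb4 was covered at 97.7% ± 3.23, Hoxb5 at 100% in each replicate, Hoxb7 at only 37.9% ± 1.04 and Hoxb8 at 93.9% ± 2.86, against 28.0% ± 0.771 at Hoxb9 and 7.93% ± 1.92 at Hoxb13. In Hoxc, Hoxc4 had the most at 38.6% ± 3.51, and Hoxc11 and Hoxc12 had no cover in either replicate. In Hoxd, Hoxd9 had 59.0% ± 6.30 and Hoxd8 47.4% ± 1.90, while Hoxd12 had none. Hoxd3 and Hoxd4, at 15.2% ± 1.19 and 16.0% ± 1.42, had about the same share as Hoxd13 at 14.7% ± 0.215. Their annotated spans are unequal, however, at 36516, 17232 and 3290 bp. Within 10 kb of the 5' end, replicated peaks covered 5.18 kb at Hoxd3 and at Hoxd4, against 1.91 kb at Hoxd13. The 5' ends of Hoxd3 and Hoxd4 lie at 74711927 and 74711929, so their windows count the same peaks. Hoxd1 had 2.29 kb in its window, less than Hoxd12 at 2.85 kb. No test was made between clusters.

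**Figure D4:**
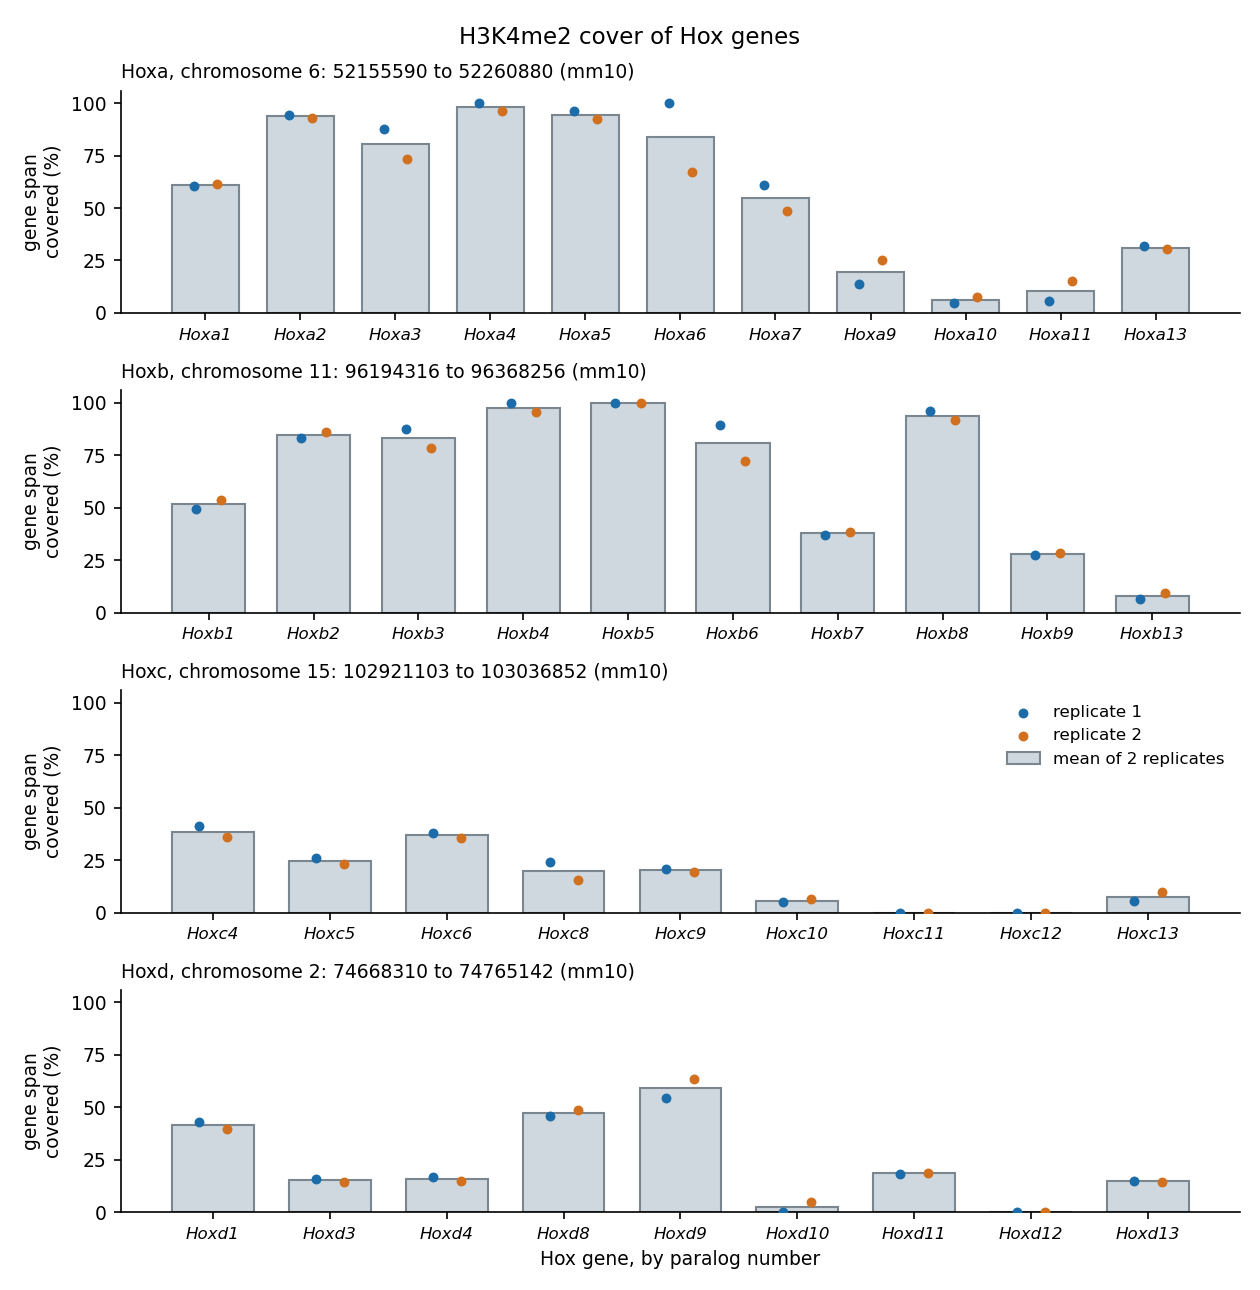
Share of each Hox gene's span covered by peaks (%), by cluster and paralog number; bars are means of 2 replicates and points are replicate 1 (blue) and replicate 2 (orange). Cover was near complete from Hoxb4 (97.7%) to Hoxb5 (100%) and at Hoxa4 (98.2%), and was 6.20% at Hoxa10 and 7.93% at Hoxb13.

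The widest domain of the mark lay over the Hoxb cluster. Peaks no more than 1 kb apart were merged into 31309 domains with a median width of 1263 bp, of which 1072 were wider than 5 kb and 77 wider than 10 kb. The widest, 55.1 kb on chromosome 11 from 96291634 to 96346702, spanned Hoxb3 to Hoxb6 and was covered over 49.5 ± 3.98 kb (n = 2). Next came domains over Nr2f2, a nuclear receptor of mesenchyme and vein (chromosome 7, 70345699 to 70371195, 25.5 kb), Hoxa1 to Hoxa3 (chromosome 6, 52156643 to 52181732, 25.1 kb), Meis2 (24.5 kb), the Hedgehog receptor Ptch1 (chromosome 13, 63551280 to 63574336, 23.1 kb), Meis1 (17.0 kb), Foxa1 (16.6 kb), Bahcc1 (16.5 kb), Gata4 (16.4 kb) and Tbx2 (16.1 kb). Of all protein-coding genes, Hoxb4 had the widest cover within 10 kb of its 5' end, at 19.4 ± 0.881 kb. Among the 20 genes with the widest cover were also Setd1b, which encodes a subunit of a histone H3 lysine 4 methyltransferase, with 15.6 ± 0.279 kb, and Zfp503, with 13.9 ± 0.425 kb. Without merging, 17 domains were wider than 10 kb and 5 of the 10 widest were met again; with gaps of up to 3 kb merged these counts were 297 and 5.

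The 5 replicated peaks of highest signal more than 10 kb from any start were found on 4 chromosomes. The strongest (chromosome 9, 77654917 to 77656200) lay inside Klhl31, a gene of striated muscle, 18.4 kb from its nearest protein-coding start. Others lay inside Tns3, an adhesion protein (chromosome 11, 8622926 to 8625782), and inside Srcin1 (chromosome 11, 97546121 to 97547593). Another (chromosome 19, 7164220 to 7166676) lay 39.6 kb from Otub1, a ubiquitin protease, but inside Macrod1, a gene named after the value was seen. The last lay 74.99 kb from Hmga2, a chromatin protein of growing tissue (chromosome 10, 120551457 to 120553734). Peaks of each replicate covered at least 84.0% of the length of each of them.

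With GC and CpG content held, the E-box and words bound by NFI, CTCF, HNF1, HNF4, TEAD and forkhead factors were more frequent in distal peaks than beside them. Forkhead factors act in gut endoderm and mesenchyme. Among 18 consensus words fixed before the data were examined, 10 were more frequent in 14507 distal peaks than in 25528 windows of the same width 5 kb to either side, with GC and CpG content held in a logistic model. Odds ratios were 2.59 (95% confidence interval 2.23 to 3.01) for NFI, 2.39 (2.05 to 2.80) for CTCF, 2.09 (1.51 to 2.88) for HNF1 and 2.01 (1.62 to 2.49) for ETS. They were 1.54 (1.46 to 1.63) for the E-box, 1.499 (1.17 to 1.92) for HNF4, 1.48 (1.39 to 1.58) for the forkhead word FOX, 1.39 (1.301 to 1.48) for TEAD, 1.09 (1.01 to 1.18) for AP-1 and 1.08 (1.03 to 1.14) for MEIS. In raw shares, without the covariates, HNF1 lay in 0.682% of peaks and 0.615% of windows, and FOX in 18.6% and 17.7%. The E-box lay in 43.5% and 27.3%, and NFI in 4.43% and 1.45%. GC content averaged 51.2% in peaks and 45.3% in windows. The odds ratios of HNF1 and FOX therefore rest largely on the covariates. The RUNX word was less frequent, at 0.786 (0.731 to 0.845). The words for GATA, SOX, SRF, homeobox, KLF, NKX and REST did not pass the test, GATA with an odds ratio of 0.991 (0.942 to 1.04). Of these words GATA, SOX, SRF, homeobox and NKX passed, as more frequent, with peak width held as a further covariate, an alternative chosen after seeing the data. SOX also passed with windows 10 kb away and homeobox in the stronger 50% of peaks. GATA passed as less frequent with the peaks of either replicate alone. Of the 10 words, 7 also exceeded every word made by shuffling their letters, the exceptions being ETS, AP-1 and MEIS, and the odds ratio of RUNX lay within the range of its shuffled words, 0.597 to 1.07. AP-1 was lost with the peaks of either replicate alone, with windows 10 kb away and with the stronger 50% of peaks, and MEIS with the stronger 50% of peaks. HNF1 and MEIS were lost with the peaks of replicate 2 alone, and 2 words stood below in place of 1 with the peaks of either replicate.

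**Figure D5:**
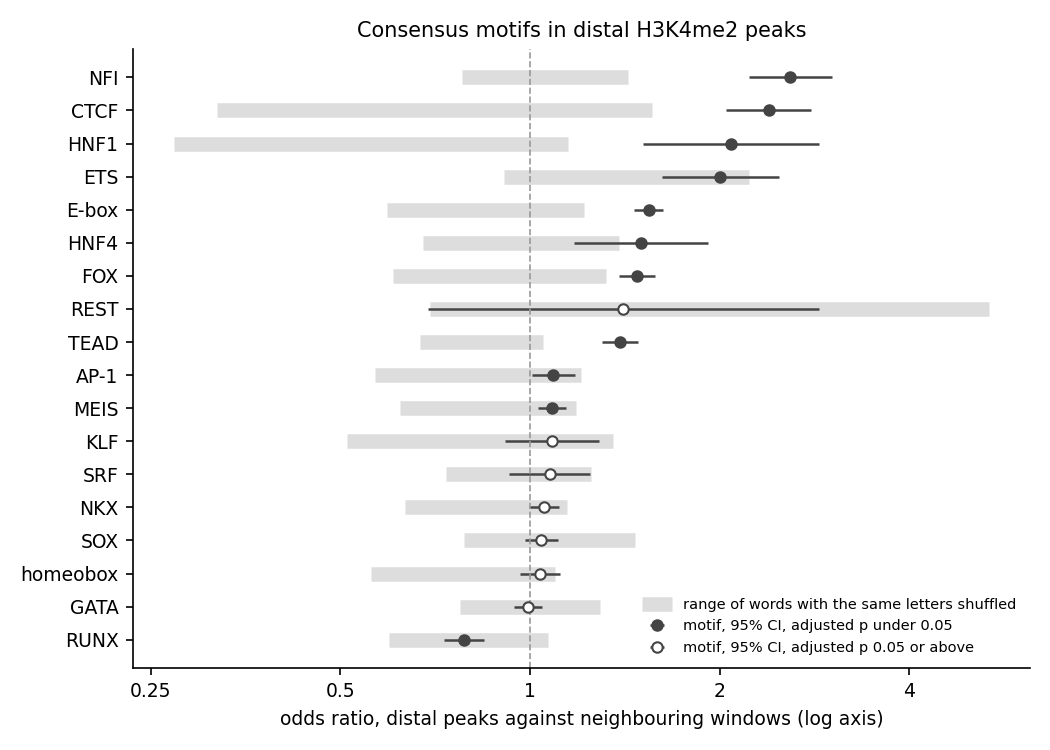
Odds ratio of each consensus word in distal peaks against neighbouring windows (log axis) with its 95% confidence interval; filled points had an adjusted p under 0.05, and grey bars span the odds ratios of words made by shuffling the same letters. NFI (2.59), CTCF (2.39) and HNF1 (2.09) lay above their shuffled words, and RUNX (0.786) lay within them.

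Genes of the X chromosome carried the mark less often than autosomal genes. A replicated promoter peak was found at 496 of 948 X genes (52.3%) and at 14597 of 20780 autosomal genes (70.2%; Fisher's exact test, two-sided, p = 1.72e-29). X genes also had fewer CpG-rich promoters: 51.7% of X genes and 39.1% of autosomal genes had a CpG ratio under 0.4. Within that class the shares were 20.2% and 29.3% (exact test, p = 9.4e-06), between 0.4 and 0.6 they were 76.5% and 89.0% (p = 1.44e-06, exact test), and above 0.6 they were 94.9% and 98.7% (exact test, p = 6.48e-05). The X chromosome held 5.56 replicated peaks per Mb and chromosome 11, the densest, 25.1, and 3 replicated peaks lay on the Y chromosome.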

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

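The tests of the ratio between replicates, of the X chromosome and of the stomach class without its mesenchymal and epithelial lists were chosen only after the result was seen; the others were planned. The design has a single group, so no biological explanation was tested. On unplaced or unlocalized scaffolds, which entered no comparison, there were 14 replicated peaks; 6 of them lay on 1 scaffold assigned to the X chromosome and 4 on scaffolds of chromosome 4, and their median signal stood at percentile 43.5 of the replicated list. They were flagged because a count over 3 in data left out of the comparisons is always flagged, which is a rule and not a test.

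Of the peaks of replicate 1, 19338 were not covered by replicate 2, and of those of replicate 2, 15445 were not covered by replicate 1. Calls near the authors' threshold are a candidate explanation: at least 96.5% of the stronger 50% of peaks were covered in each replicate, and at most 45.7% of the weaker 50%. Repeat sequence is argued against, since within the classes of signal, of 10, that held at least 20 covered and 20 uncovered peaks (7 in replicate 1 and 6 in replicate 2) the soft-masked share of uncovered peaks exceeded that of covered peaks by a median of at most 1.16 percentage points. For tissue of a neighbouring organ in 1 pool, the planned test gave a replicate difference of -21.7% of the neighbouring organ mean against the stomach class (95% interval -35.8 to -7.22, permutation p = 0.0127), but the stomach class has more cover and so gains more kb from the same relative widening. By the ratio of replicate 1 to replicate 2 the classes stood at 114% each and differed by 0.284 percentage points (95% interval -11.9 to 11.6, permutation p = 0.937), an interval too wide to exclude 10 points, so this explanation stays open.

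Cover was wider around genes of the stomach tissue lists than around genes of other tissues, by 2.14 kb. With promoter CpG content held in a linear model the difference was 1.99 kb (interval of 2 SE 1.13 to 2.84, permutation p = 1e-04, the smallest that 10000 permutations can give), and with the number of genes in the window held it was 2.24 kb (1.22 to 3.27, permutation p = 1e-04). Both argue against promoter CpG content or gene density as the whole of the difference. Without the mesenchymal and epithelial lists, an alternative chosen after the result was seen, it was 0.534 kb (SE 0.304, permutation p = 0.114) in place of 2.14 kb (SE 0.356); the call ended because the stomach mean went from 4.04 to 2.43 kb. The choice of genes may therefore account for the difference between the classes and stays open: the lists mix regulators with products of mature cells, and the secretory list of the stomach itself stood at 0.839 kb.

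Fewer genes had a promoter peak on X than on autosomes. Against autosomal genes matched on promoter CpG content the difference was -10.6 percentage points (permutation p = 0.0002). That is the smallest p that 10000 permutations can give in this test, where the smaller tail is doubled. CpG content may therefore account for part of the -17.9 points but not for all. Next, 273 X genes and 5339 autosomal genes were left out. Their symbols shared their opening letters with many others of the same chromosome, or were only predicted or Rik clone names. The rule goes by name and not by sequence, so it can take in genes that are not copies of each other. Without these genes the matched difference was -5.71 points (permutation p = 0.0002), at 69.6% of X genes against 75.3%. The genes left out may therefore contribute. How far reads that cannot be placed among copies play a part was left open, because no reads were analysed here. A single X chromosome in male embryos of the mixed pools is a further explanation that could not be tested.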

How the results depend on the processing

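Alternatives chosen after seeing the data were those of the overlap at 1 bp in classes of strength, the CpG classes, each replicate's own list for Hox clusters, other lists for domains, the X chromosome by CpG class, the peak width and shuffled words for motifs, the stomach class without its mesenchymal and epithelial lists, and the replicated peaks that meet the overlap rule with both replicates; all others were planned. Of the alternative values of the main results, 121 stayed within 1.5 times, the spread or the interval of the reported value or kept their side of the threshold, 24 did not and 1 ceased to pass it, the stomach class against other tissues without its mesenchymal and epithelial lists, at 0.534 kb; for single lists and motifs 444 kept their direction and their side of the threshold, 23 came to pass it, 36 ceased to pass it and 47 changed sign. Replicate overlap needs both replicates and has no value without one. Where a value moved, the cause was not tested, unless the alternative's own construction shows it. With an overlap of 1 bp, covered shares were 98.8% and 99.3% in the stronger and 44.8% and 54.5% in the weaker 50% of replicates 1 and 2. Lists below other genes by promoter peak numbered 8 in the stronger 50% of peaks, 1 against CpG-matched genes and 3 to 5 without a replicate. Lists below by covered length numbered 7 at 5 kb, 8 by domain width and 1 against CpG-matched genes, and lists above by distal peaks 2 in the stronger 50%. The share of genes under a CpG ratio of 0.4 that had a promoter peak was 30.7% in the pooled list and 29.8% without either replicate. In the pooled list Hox cover was 58.9%, 42.0%, 20.7% and 20.3% in Hoxa, Hoxb, Hoxc and Hoxd. Domains over 10 kb numbered 17 without merging and 297 with gaps of 3 kb, each meeting 5 of the 10 widest. Words less frequent in distal peaks numbered 2 without either replicate.

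Signs turned mostly in lists and words that passed the test under neither setting. Against all other genes, the difference in marked promoters (percentage points) became, for endothelium, 9.96 in the pooled list, 19.9 at 2.5 kb and 0.428 to 10.4 without a replicate; for mesothelium, -5.51 in the stronger 50%; for cardiac muscle, 0.428 at 500 bp and 4.91 at 2.5 kb; and for skeletal muscle, 0.496 at 2.5 kb. Against CpG-matched genes it became 1.47 for erythroid cells, 5.31 for intestinal epithelium, 0.457 for pancreas and 10.2 for cardiac muscle, of which only intestinal epithelium had been called. The difference in covered length (kb) became -0.219 for endothelium, -0.849 for pancreas and -0.174 for the central nervous system in the stronger 50%, and 0.196 for leukocytes and 0.333 for erythroid cells against CpG-matched genes. For mesothelium it became 0.142 in the pooled list, 0.154 at 5 kb and -0.0895 to 0.00313 without a replicate, and for pancreas -0.0912 at 5 kb, -0.160 by domain width and -0.103 to 0.199 without a replicate. The difference in distal peaks per gene became, in the stronger 50%, -0.0957 for forestomach, -0.0223 for smooth muscle, -0.0656 for enteric neurons and 0.179 for hepatocytes. In the pooled list it became 0.351 for mesothelium, 0.0993 for hepatocytes and -0.0154 for germ cells, and at 100 kb 0.0507 for hepatocytes and -0.00504 for germ cells. For hepatocytes it was also 0.0122 with the overlap rule met and 0.00954 against CpG-matched genes. Without a replicate it ranged over -0.0208 to 0.117 for secretory genes, -0.0679 to 0.00229 for mesothelium, -0.0826 to 0.244 for hepatocytes and -0.472 to 0.516 for germ cells. The log2 odds ratio of GATA became 0.0094 with windows at 10 kb, 0.042 in the stronger 50% and 0.10 with peak width held, where it passed the test. Without a replicate the log2 odds ratio ranged over -0.021 to 0.025 for SOX, -0.048 to 0.12 for SRF, -0.063 to 0.047 for AP-1, which had been called, -0.040 to 0.025 for homeobox, -0.042 to 0.036 for KLF and -0.017 to 0.029 for NKX.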

Other observations

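All values in this part were computed after the data were seen. Families of regulators, chosen after the data were seen, had different lengths of cover, and no difference between them was tested. The 7 Meis and Pbx genes, partners of Hox proteins, averaged 8.94 kb of cover within 10 kb of the 5' end in the replicated list (replicates 8.62 ± 0.374 kb, n = 2), the 4 Id genes, inhibitors of bHLH factors, 7.88 kb (7.63 ± 0.428), the 8 Hes and Hey genes, targets of Notch, 6.17 kb (5.81 ± 0.188) and the 3 Gli genes, effectors of Hedgehog signalling, 5.76 kb (5.48 ± 0.404), against 2.28 kb for all protein-coding genes and 3.38 kb for those with a CpG ratio over 0.6. All members of these 4 families had a promoter peak, as did 98.5% of genes with a CpG ratio over 0.6; the median ratio of the families lay between 0.585 and 0.715. So did all 19 Sox genes, with 5.08 kb (4.76 ± 0.319), the 6 Iroquois genes, with 5.47 kb (4.90 ± 0.145), and the genes Six1 to Six6, with 5.38 kb (5.01 ± 0.279). Of 44 Fox genes 40 were marked, the exceptions being Foxb1, Foxi1, Foxr1 and Foxr2, and of 13 T-box genes 10, the exceptions being Tbx4, Tbx10 and Tbx19. Lower cover was found in the LIM homeobox genes, with 3.04 kb (2.65 ± 0.0809) and 7 of 8 marked, and in the Dlx genes, with 3.00 kb (2.83 ± 0.0138). Pax genes stood at 2.27 kb (2.21 ± 0.0251), close to all genes. Of the Nkx genes 12 of 14 were marked, of the Gata genes 5 of 6 and of the Klf genes 16 of 17. Histone cluster genes averaged 6.76 kb (6.36 ± 0.416), and lie close together, so that 1 window can hold several.

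Some families with promoters poor in CpG were almost bare, against the 28.3% of all genes with a CpG ratio under 0.4 that had a promoter peak. The median CpG ratio was 0.106 in olfactory receptors, 0.0914 in vomeronasal receptors, 0.166 in keratin-associated proteins and 0.116 in beta-defensins. A promoter peak was found at 6 of 1134 olfactory receptor genes (0.529%), 1 of 330 vomeronasal receptor genes, 1 of 57 genes of keratin-associated proteins, and at none of 42 beta-defensin genes, 25 genes of the prolactin family and 34 Rhox genes, the reproductive homeobox cluster of the X chromosome. Among cytochrome P450 genes, with a median CpG ratio of 0.150, 30 of 100 were marked, close to the share of that CpG class, and the retinoic acid hydroxylase Cyp26b1 had the widest cover of them.

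Of 10061 genes with a 5' end rich in CpG, 148 had no replicated promoter peak and 134 of these had none in either replicate. Of the 148, 98 had symbols other than those of predicted (Gm) or Rik clone genes, though some, such as CN725425, are still clone symbols. Of the 148, 13 lay on X and 5 on Y. Some were near-identical copies, such as Entpd4 and Entpd4b (CpG ratio 0.804 each) and Srp54b and Srp54c (0.778 each), and no reads were analysed here to show whether they can be placed among copies. Others, picked by eye and not tested as a group, were Sycp1, Sycp2, Sycp3, Hormad1, Mael, Ddx4, Asz1 and Mov10l1, genes of the protocadherin alpha cluster of neurons, and the homeobox genes Hoxc11, Hoxc12, Evx2, Dbx1 and Lhx5. Without a promoter peak, some of them still had replicated peaks within 10 kb of the 5' end. Cover there was 3.355 kb at Dbx1, 3.20 kb at Lhx5, 2.475 kb at Sycp2, 2.25 kb at Evx2 and 1.51 kb at Ddx4. Sycp1, Sycp3, Hormad1, Mael, Asz1, Mov10l1 and Hoxc11 had none in the replicated list. Of the 5 germ cell list members with CpG-rich promoters, 2 had a peak. At the other end, some genes with few CpG at the 5' end had wide cover, with no other protein-coding gene's 5' end in the window. Among them were Nr2f2 with 13.4 ± 0.267 kb, the H3K27 demethylase Kdm6b with 13.1 ± 0.494 kb and Hoxb2 with 12.2 ± 0.150 kb. The collagen gene Col1a1 had 11.1 ± 1.78 kb and Pdgfra, a receptor of mesenchyme, 9.65 ± 0.730 kb (n = 2 each). Further starts of the same gene and starts of non-coding genes were not counted.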
